A study of Rattus norvegicus with 4 samples.

How the data were processed

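Total RNA of the rat left ventricle had been hybridised to 4 Affymetrix arrays of the rat genome U34 set (array A), 1 for each of SD control, dTGR, losartan-treated dTGR and terminal heart failure. The deposited table gives 1 intensity per probe set and array, on a linear scale. The software that made these values, its version, detection calls, doses, ages and the number of animals behind each array are not given in the sources used here, and whether RNA was pooled is not stated. The deposited values were already on a common scale: with the lowest and highest 2% of probe sets left out, the mean intensities were 200.2, 200.3, 200.2 and 200.2 for terminal heart failure, dTGR, losartan-treated dTGR and SD control, and the medians were 38.7, 47.4, 40.2 and 40.1. Maxima were 20728, 49747, 28463 and 22575. Of 35196 values, 15281 lay from 1 to under 32, and 13625 of these had a 0 as first decimal and a digit from 1 to 9 as second, 1551 were whole numbers and 105 had decimals that form no day and month. None of the 19632 values of 32 or more had that form. Low values thus appear to have been rewritten as day and month by a spreadsheet, which moves a value by less than 1 intensity unit, and values under 32 lie under or near the floor used here.

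The instrument records that came with each array gave the batches. The dTGR and SD control arrays shared a chip lot, the terminal and losartan arrays shared another, the terminal array was run on a day of its own, and the dTGR array had its own fluidics protocol. Of the 5 comparisons below, dTGR against SD control was the only one within a chip lot, those with terminal heart failure were between run days and those with dTGR were between fluidics protocols. Within such a comparison the differing factor was not separate from the group. Ratios of 3' to 5' signal for Gapdh were 1.28, 1.73, 2.17 and 1.34 for terminal, dTGR, losartan and SD control, and those for actin were 1.63, 2.07, 2.26 and 1.46. The 100 most intense probe sets held 31.8%, 46.3%, 36.9% and 32.9% of the total signal. Spearman correlations over probe sets between the dTGR array and the others were 0.859 to 0.878, and those among the others 0.892 to 0.921.

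Each array was scaled to the mean of the 4 trimmed means, values under the 40th percentile of all pooled values (26.0) were set to that floor, and log2 was taken. Of 8799 probe sets, 59 controls, 1426 with no gene symbol and 308 with several were left out, and 7006 remained for 4736 genes, of which 1565 had 2 or more probe sets. The identifiers of 6985 probe sets matched the rat gene table, and 0 symbols needed an update. A gene was represented by its probe set with the highest mean. Agt, the rat angiotensinogen gene, lay near the floor (intensity 39.1 in SD control, 37.7 in dTGR). A gene counted as higher or lower when it was above the floor on at least 1 of both arrays and differed at least 2-fold. A fold with 1 side under the floor is a lower bound.

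With 1 array per group no test, p-value or interval for animals was possible, and none is given. The 5 comparisons were dTGR against SD control, terminal heart failure against SD control and against dTGR, and losartan-treated dTGR against dTGR and against SD control. The number of genes expected past 2-fold from measurement alone was simulated from the differences between probe sets of the same gene, in 200 simulated sets to which the same floor was applied. For each of 23 gene lists and 13 lists of cell type markers, the median log2 difference of members above the floor was placed among 10000 random lists of the same size, matched on mean level in 10 bins (seed 1). Lists, comparisons, thresholds, the rule for named genes and 10 alternative settings were fixed before the data were examined. The rule named, per comparison, the 10 genes with the largest positive and the 10 with the largest negative difference past 2-fold that were above the floor on both arrays and had no probe set of the other sign there, with predicted genes left out. It also named up to 4 members of each list with the largest difference, whether or not they reached 2-fold, and Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2 and Agt, and 1 further gene that is not reported here. The pairing of arrays, the correlations between pairs with no shared array, the overlap with the losartan array, the values after losartan of genes above the floor on 3 arrays, the floor in the simulated gene counts, list medians after quantile normalization and cyclic loess beside the reported ones, and the reading of low values as 1 decimal were added after seeing the data.

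The gene lists were hypertrophy and fetal program markers, adult contraction and calcium handling, extracellular matrix and fibrosis, fatty acid oxidation, fasting and ketone responses, glycolysis and glucose uptake, the tricarboxylic acid cycle, oxidative phosphorylation, acute phase and inflammation, antigen presentation and interferon response, circadian clock, renin-angiotensin and natriuretic systems, adrenergic signalling, ion channels, proteolysis, heat shock, immediate early genes, antioxidant and heme genes, cytochrome P450 and eicosanoid metabolism, glucocorticoid responsive genes, the insulin-like growth factor axis, the cell cycle and ribosomal proteins. The marker lists were cardiomyocyte, atrial or conduction tissue, fibroblast, vascular smooth muscle, endothelium, macrophage, lymphocyte, mast cell and granulocyte, erythrocyte and platelet, adipocyte, skeletal muscle, liver and nerve. Some genes stand on more than 1 list.

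The procedure was tested on simulated data for terminal heart failure against SD control, with genes of known difference planted in 20 simulations. It called 20.1% of genes planted at 1.5-fold, 46.9% at 2-fold, 84.9% at 3-fold and 93.7% at 4-fold, with the right sign in 89.9%, 96.2%, 99.1% and 99.7%. Of 4536 genes with no planted difference, 236.9 were called on average with the spread pooled over all 5 comparisons, so a gene just past 2-fold is often noise. Lists of 20 genes planted at 2-fold lay outside the random range in 20 of 20 simulations, and lists with no planted difference in 2 of 20.

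Alternative settings were the values as deposited, scaling to the same median, quantile normalization, cyclic loess (span 0.7, 3 iterations), floors at the 25th and 60th percentile, no floor with an offset, the median of a gene's probe sets, every probe set on its own, a 3-fold threshold and low values read as 1 decimal. R 4.3.3 with limma 3.58.1 did quantile normalization and cyclic loess, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the rest.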

Results

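Gene expression was measured in total RNA of the rat left ventricle on 4 oligonucleotide arrays, with 1 array for each of 4 groups and no replicates. The groups were a Sprague Dawley control (SD control), double transgenic rats that carry human renin and human angiotensinogen (dTGR), dTGR treated with losartan, a blocker of the angiotensin II type 1 receptor, and terminal heart failure. The label of the terminal sample does not itself name a genotype, and all 4 samples carry the same description of the dTGR rat, which develops hypertension and heart hypertrophy. Each array gave an intensity for 8799 probe sets, of which 58.36% to 63.73% lay above the floor of 26.0 that was used as the lower limit of measurement. Values from 1 array per group have no error between replicates, so the differences below are sizes of change with no test, and the number of arrays limits their precision. A list median is therefore set against random gene lists of the same size and level on the same arrays, as a description of these arrays and not of a group of animals. Each percentile states the share of 10000 such random lists with a lower median, and the range of their central 95% is called the random range.

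The first comparison asked how the ventricle of the hypertensive transgenic rat differed from that of the control. Nppa, the precursor of atrial natriuretic peptide, a hormone made by stretched cardiomyocytes, had an intensity of 22028 in dTGR and 1759 in SD control, 12.5-fold higher. Reg3b, a secreted lectin of the acute phase, was 12.2-fold higher, and Penk, the precursor of enkephalin peptides, was 9.18-fold higher. Genes of acute phase and inflammation and genes of the hypertrophy program were higher as groups, with list medians of 0.49 and 0.93 on the log2 scale. Genes of fatty acid oxidation were lower as a group, with a median of -0.30.

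**Figure D1:**
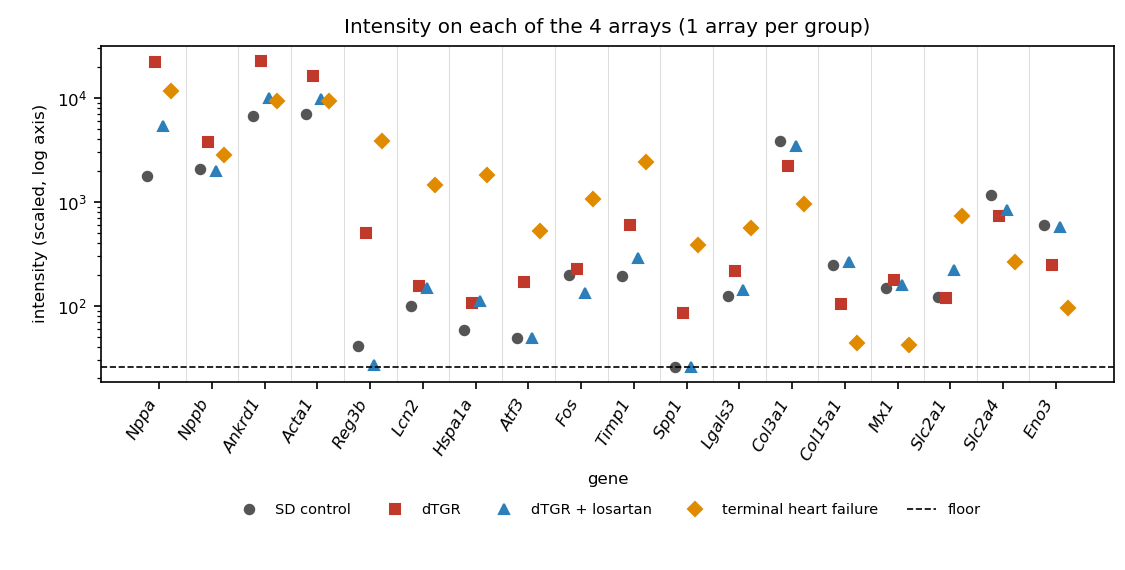
Intensity of 18 named genes (x axis) on each of the 4 arrays (y axis, log scale, intensity units), 1 symbol per array, with values under the floor drawn at the floor of 26.0 (dashed line). Nppa stood highest in dTGR (22028) and lowest in SD control (1759), and Reg3b stood highest in terminal heart failure (3849).

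Of the 9 hypertrophy and fetal program genes above the floor, 4 were at least 2-fold higher in dTGR and 0 were lower, and the list median stood at percentile 99.99. Ankrd1, a stress-responsive protein of the sarcomere, was 3.39-fold higher, Tpm2, the gene of beta-tropomyosin, was 2.56-fold higher, and Acta1, the skeletal alpha-actin expressed in the fetal heart, was 2.31-fold higher. Ankrd1 and Acta1 were bright (22690 and 16092 in dTGR), and the top 2% of genes by level had a median of 0.45 above SD control. After quantile normalization the list median was 0.72, at percentile 99.99. Nppb, the precursor of brain natriuretic peptide, was 1.86-fold higher. Of the 44 acute phase and inflammation genes, 8 were higher and 0 lower, at percentile 100, including Il6st (3.05-fold), the signalling subunit of the interleukin 6 receptor, and Cebpb (2.78-fold), a transcription factor of the acute phase. Among 19 immediate early genes, 3 were higher and 0 lower (median 0.39, percentile 99.89), with Atf3, a stress-induced transcription factor, 3.40-fold higher. Of 10 macrophage markers, 1 was higher and 0 lower (median 0.49, percentile 98.67), and Lyz2, a lysozyme of macrophages, was 1.80-fold higher. Hmox1, which encodes heme oxygenase 1, was 2.88-fold higher on its list of 29 antioxidant, metallothionein and heme genes, where 1 was higher and 0 lower (median 0.21, percentile 99, with a median of -0.03 after scaling to the same median).

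Of 28 fatty acid oxidation genes, 0 were at least 2-fold higher and 1 was lower, with the list median at percentile 0.02. Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, was 2.04-fold lower, and Eci1, an isomerase of the same pathway, was 1.81-fold lower. Among 8 fibroblast markers, 1 was higher and 1 lower (median -0.59, percentile 0.16), with Col1a1 and Col3a1, the main fibrillar collagens, 2.13-fold and 1.71-fold lower. Other probe sets of Col1a1 had log2 differences from -0.75 to -0.29, short of 2-fold. In the list of 7 circadian clock genes, 1 was lower and 0 higher (median -0.70, percentile 1.37), and Bmal1, the core clock activator, was 2.54-fold lower. Matrix genes went both ways. Of 40 extracellular matrix and fibrosis genes, 7 were higher and 2 lower, the median of 0.02 lay inside the random range, and Thbs4, a matrix glycoprotein of stressed hearts, was 5.29-fold higher. Spp1, which encodes osteopontin, was at least 3.31-fold higher, since its value in SD control lay under the floor.

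Genes of adult contraction and calcium handling were also higher, with 4 of 19 at least 2-fold higher and 0 lower (median 0.59, percentile 100), and so were 7 cardiomyocyte markers, with 2 higher (median 0.92, percentile 99.97). These lists hold the most abundant transcripts of the heart, and on the dTGR array all 95 genes of the top 2% by level had a median of 0.45 above SD control. After quantile normalization the medians were -0.07 and -0.10 and lay inside the random range, and cyclic loess also put both inside it. The dTGR array was the only one run with another fluidics protocol, with 0 wash cycles and 0 seconds of first stain where the other 3 arrays had 10 and 4 cycles and 600 seconds. Slc8a1, the sodium-calcium exchanger, was 3.47-fold higher and Actc1, the cardiac alpha-actin, was 2.55-fold higher, the latter with no difference (0.00) after quantile normalization. Atp2a2, the calcium pump of the sarcoplasmic reticulum, was 1.75-fold higher but had a log2 difference of -0.23 after quantile normalization, and its other 3 probe sets ranged from -0.59 to 0.29. Probe sets that share sequence within the myosin heavy chain family stood for Myh6 and Myh7, the alpha and beta heavy chains, which were 1.53-fold and 1.90-fold higher, with log2 differences of -0.20 and -0.08 after quantile normalization. Other probe sets gave log2 differences of 2.09 for Myh7 and of -1.74 and 0.02 for Myh6, so the direction of Myh6 was not settled.

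In all, 278 genes were at least 2-fold higher in dTGR and 212 were lower, among 3614 genes above the floor on at least 1 of both arrays. The spread between probe sets of the same gene (SD 0.53 on the log2 scale), simulated with no effect and the same floor, would by itself give 142.0 and 142.4 such genes. Above the floor on both arrays were 146 higher and 134 lower genes, where the simulation gave 110.9 and 111.3, a smaller excess. Among genes above the floor on both arrays, the 535 in the lower 50% by level had a median of 0.23, against -0.01 over all such genes. Low signal was thus higher on the dTGR array, and whether this added higher calls near the floor was not tested. Where a called gene had a probe set other than the one used, that probe set had the same sign in 41 of 56 genes (73.2%). Scaling to the same median gave 159 higher and 379 lower, and quantile normalization gave 215 and 247. Besides Nppa, Reg3b, Penk and Thbs4, the genes with the largest higher values were Cdo1, Trdmt1, Scarb1, Pitx3, Akip1 and Foxm1, from 3.70-fold to 7.88-fold. Those with the largest lower values were Dtd1, Casz1, Casp2, Pde4a, Crmp1, Lrba, Esr2, Pde4c, Bmyc and Fam83f, from 3.52-fold to 4.92-fold. Casp2 went the other way on another probe set, with a log2 difference of 1.45, a bound since the SD control value lay under the floor. The medians of the immediate early and clock lists lay inside the random range with the floor at the 25th or the 60th percentile. The median of the antioxidant list did so after cyclic loess and with the median of a gene's probe sets, and the latter also put the contraction list inside.

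The second comparison set terminal heart failure against SD control. Reg3b was 93.4-fold higher, at 3849 against 41.2, and Hspa1a, a stress-inducible chaperone, was 31.6-fold higher. Genes of the acute phase, immediate early genes and glucocorticoid responsive genes were higher as groups, with medians of 0.98, 0.90 and 1.15. These lists overlap. Of the glucocorticoid list, Cebpd and Nfkbia also stand on the acute phase list, and Sgk1 and Dusp1 on the immediate early list. The glucocorticoid median is therefore not independent of the others. Genes of antigen presentation and the interferon response were lower as a group, with 10 of 19 at least 2-fold lower and 0 higher (median -1.03). Genes of fatty acid oxidation, glycolysis and the cell cycle were lower too, while ribosomal protein genes and macrophage markers were higher.

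Of 38 acute phase and inflammation genes, 19 were at least 2-fold higher and 1 was lower, at percentile 100. Lcn2, an iron-binding protein secreted in inflammation, was 14.8-fold higher, Cebpb was 10.7-fold higher and Cebpd, a related transcription factor, was 6.84-fold higher, although another probe set of Cebpd had a log2 difference of -0.31. Among 21 immediate early genes, 10 were higher and 1 lower, at percentile 100. Atf3 was 10.7-fold higher, Myc 5.85-fold higher, Fos 5.31-fold higher and Dusp6, a phosphatase that limits ERK signalling, 4.42-fold higher. The 10 glucocorticoid responsive genes included 5 that were higher and 0 lower, at percentile 100, among them Errfi1 (4.06-fold) and Nfkbia (2.87-fold), an inhibitor of NF-kappaB. In the list of 26 heat shock and endoplasmic reticulum stress genes, 5 were higher and 0 lower (median 0.16, percentile 98.67), with the chaperone Dnajb1 2.55-fold higher. Of 29 antioxidant, metallothionein and heme genes, 3 were higher and 3 lower (median 0.17, percentile 99.45), with Hmox1 4.62-fold higher and Alas1, the first enzyme of heme synthesis, 3.54-fold lower.

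Within the antigen presentation and interferon list, whose median stood at percentile 0.0, Mx2 and Mx1, interferon-induced antiviral proteins, were 4.38-fold and 3.56-fold lower, and Irf7, a regulator of interferon genes, was 2.67-fold lower. Of 9 macrophage markers, 4 were higher and 1 was lower (median 0.97, percentile 99.98). Lgals3, the gene of galectin 3, was 4.47-fold higher, Lyz2 was 3.64-fold higher and C1qb, a subunit of complement C1q, was 2.56-fold higher, whereas Cd74, the invariant chain of class II antigen presentation, was 2.30-fold lower. The cell cycle list had 1 of 18 genes higher and 5 lower (median -0.72, percentile 0.06), with Ccnd1 and Ccne1, cyclins of the G1 phase, 2.75-fold and at least 7.71-fold lower, although another probe set of Ccnd1 had a log2 difference of 0.05. Another probe set of Ccne1, above the floor on both arrays, had a log2 difference of -0.50. Ccnd2, a related cyclin, was the 1 higher gene (5.23-fold, with a log2 difference of 0.35 on another probe set). Of 39 ribosomal protein genes, 5 were higher and 0 lower (median 0.28, percentile 100), including Rpl17 (6.83-fold) and Rpl3 (2.44-fold). Proteolysis genes had 2 of 32 higher and 1 lower (median 0.12, percentile 97.94), with the lysosomal protease Ctsl 3.57-fold higher.

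Nppa was 6.67-fold higher than in SD control, and the hypertrophy and fetal program list had 3 of 10 genes higher and 0 lower (median 0.47, percentile 99.84). Csrp3, the muscle LIM protein of the Z disc, was 2.18-fold higher, while Nppb was 1.36-fold and Acta1 1.33-fold higher. The contraction and calcium handling list had 0 of 19 genes higher and 1 lower, with its median of -0.22 inside the random range. Cacna1c, the pore of the cardiac L-type calcium channel, was 2.07-fold lower. Atp2a2 was 1.13-fold lower, with other probe sets from 0.08 to 0.59 on the log2 scale. Myh6 was 1.21-fold lower and Myh7 1.09-fold higher, and other probe sets gave log2 differences of -1.27 and -1.26 for Myh6 and of 0.97 for Myh7. The 7 cardiomyocyte markers had a median of -0.14, equal to that of matched random lists (-0.14). Markers of atrial tissue (1 of 4 higher, median 0.57, percentile 98.18) and of skeletal muscle (2 of 9 higher, median 0.42, percentile 98.48) were higher.

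In the extracellular matrix and fibrosis list, 9 of 42 genes were higher and 7 lower (median 0.26, percentile 99.99). Timp1, an inhibitor of matrix metalloproteinases, was 12.5-fold higher, Thbs4 was 4.93-fold higher and Spp1 was at least 14.8-fold higher. Collagens of the list went both ways, with Col15a1, a basement membrane collagen, 5.66-fold lower and Col3a1 4.02-fold lower, while Col8a1 (3.62-fold) and Col5a2 (1.45-fold), both picked after their values were seen, were higher. Col8a1 lay near the floor in SD control (27.1). Col1a1 and Col1a2, also picked after their values were seen, were lower. The log2 differences were -1.08 to -1.43 over the probe sets of Col1a1 and -0.42 for Col1a2. The 9 fibroblast markers, of which 1 was higher and 3 were lower, had a median of -0.42 inside the random range. Among 21 glycolysis and glucose uptake genes, 2 were higher and 5 lower (median -0.43, percentile 0.975). The insulin-responsive glucose transporter Slc2a4 was 4.33-fold lower, the muscle enolase Eno3 6.31-fold lower and the muscle phosphofructokinase Pfkm 3.77-fold lower, while the basal glucose transporter Slc2a1 was 5.94-fold higher. Of 29 fatty acid oxidation genes, 2 were higher and 3 lower (median -0.41, percentile 0.60). Pdk4, a kinase that inhibits pyruvate dehydrogenase, was 3.84-fold higher and Ucp3, a mitochondrial carrier, was 2.18-fold lower.

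In all, 215 genes were at least 2-fold higher in terminal heart failure and 283 were lower, among 3371 genes, where probe set spread alone (SD 0.51) would give 84.4 and 86.2. Above the floor on both arrays were 172 higher and 210 lower genes, where the simulation gave 72.3 and 73.3. Another probe set had the same sign in 105 of 115 called genes (91.3%). Besides genes already named, the most strongly higher were Pdlim5, Trh and Plb1, from 6.83-fold to 8.37-fold, and the most strongly lower were Smim5, Gstk1, Pfkfb4, Lbh, Tmem218, Bmyc and Slc37a1, from 4.37-fold to 6.16-fold. The median over all genes was -0.14 on this array pair, and list percentiles are relative to random lists that carry the same shift. Cyclic loess gave 260 higher and 218 lower. The terminal array and the SD control array came from different chip lots and different run days. Against the losartan-treated dTGR array, which shared the chip lot of the terminal array, 253 genes were higher and 250 lower in terminal heart failure. Of these, 150 higher and 130 lower genes were also called against SD control, where a simulation with no effect and 1 shared array gave 36.7 and 25.7. The glycolysis median lay inside the random range with the floor at the 60th percentile, the proteolysis median with the floor at the 25th, and both with the median of a gene's probe sets, as did the antioxidant and atrial medians. The skeletal muscle median did so with either floor and with no floor.

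The third comparison set terminal heart failure against dTGR. Stress and inflammation genes were again higher in terminal heart failure, led by Hspa1a (17.1-fold), Lcn2 (9.50-fold) and Reg3b (7.65-fold). Pla2g4a, the cytosolic phospholipase that releases arachidonic acid, was 7.93-fold higher, and Lox, which crosslinks collagen, was 5.47-fold higher. Contractile genes and cardiomyocyte markers were lower on this scale, but their medians lay inside the random range after quantile normalization. After cyclic loess the contractile median stayed outside that range and the cardiomyocyte median did not. Jph2, which holds the calcium release units of cardiomyocytes together, was 4.0-fold lower. Nppa was 1.88-fold lower, with a log2 difference of 0.14 in the other direction after quantile normalization.

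Of 45 acute phase and inflammation genes, 15 were higher and 2 lower (median 0.43, percentile 100), including Socs3, an inhibitor of interleukin 6 signalling, at least 5.71-fold higher. Among 22 immediate early genes, 8 were higher and 1 lower (median 0.59, percentile 100), with Klf6 4.88-fold and Fos 4.67-fold higher. Of 10 glucocorticoid responsive genes, 5 were higher and 0 lower (median 1.19, percentile 100), among them Cdkn1a, a cell cycle inhibitor, at least 6.90-fold higher, Errfi1 (5.69-fold) and Pdk4 (5.55-fold). Another probe set of Cdkn1a, above the floor on both arrays, had a log2 difference of 0.53. Heat shock genes had 6 of 26 higher and 1 lower (median 0.31, percentile 99.93), with Dnaja1 2.48-fold higher. Of 10 macrophage markers, 3 were higher and 2 lower (median 0.58, percentile 99.76), and C1qc, another subunit of complement C1q, was 2.72-fold higher. Ribosomal protein genes had 4 of 39 higher and 0 lower (median 0.24, percentile 100), with Rps24 2.43-fold higher. In the matrix list, 6 of 42 genes were higher and 5 lower (median 0.22, percentile 99.87), with Timp1 4.06-fold, Spp1 4.47-fold and Col5a2, a fibrillar collagen, 2.74-fold higher.

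Antigen presentation and interferon genes were lower, with 5 of 19 lower and 0 higher (median -0.75, percentile 0.01), Mx1 4.23-fold lower and Psmb9, a subunit of the immunoproteasome, 2.67-fold lower. The cell cycle list had 3 of 19 genes higher and 4 lower (median -0.70, percentile 0.13), with Ccnb1, the mitotic cyclin, 2.63-fold lower and Pcna, the sliding clamp of DNA replication, 3.12-fold higher. In the contraction and calcium handling list, 7 of 19 genes were lower and 0 higher (median -0.80, percentile 0.0), and 5 of 7 cardiomyocyte markers were lower (median -1.04, percentile 0.095). After quantile normalization these medians were -0.10 and 0.04 and lay inside the random range. After cyclic loess the contraction median was -0.32 (percentile 2.235), still outside it, and the cardiomyocyte median was -0.37 (percentile 5.635), inside it. The contraction median stayed outside under 8 of 9 alternative settings. Hypertrophy and fetal program genes had 1 of 10 lower and 0 higher (median -0.62, percentile 2.18), with Ankrd1 2.41-fold lower. That median was 0.07 after quantile normalization and lay inside the random range under 5 of 9 alternative settings. The top 2% of genes by level had a median of -0.50 in this comparison, and the dTGR array had the other fluidics protocol.

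In all, 277 genes were at least 2-fold higher in terminal heart failure than in dTGR and 426 were lower, among 3604 genes, where probe set spread alone (SD 0.56) would give 146.8 and 146.3. Above the floor on both arrays were 193 higher and 255 lower genes, where the simulation gave 114.0 and 113.5. Another probe set had the same sign in 99 of 117 called genes (84.6%). Quantile normalization gave 334 and 336, and scaling to the same median gave 442 higher and 226 lower. Further strongly higher genes were Plb1, Tgm1 and Slc2a1, from 6.05-fold to 8.20-fold, and the most strongly lower were Trdmt1, Hbe2, Smim5, Pfkfb4, Grk1, Slc25a26, Pcp4l1 and Plcl1, from 4.02-fold to 5.89-fold. The matrix median lay inside the random range after cyclic loess, the cardiomyocyte median did so too, and the macrophage median did so with the floor at the 25th or 60th percentile.

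The fourth comparison asked how the losartan-treated dTGR ventricle differed from the untreated one. Reg3b was 18.6-fold lower after losartan, at 27.1 against 503, and Nppa was 4.08-fold lower. Hypertrophy genes, immediate early genes, acute phase genes and matrix genes were lower as groups after losartan, with medians of -0.86, -0.52, -0.39 and -0.28. Fatty acid oxidation genes and fibroblast markers were higher as groups, with medians of 0.32 and 0.63.

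Of 9 hypertrophy and fetal program genes, 3 were at least 2-fold lower and 0 higher, at percentile 0.04. Ankrd1 was 2.28-fold lower, Nppb 1.91-fold lower and Tpm2 at least 6.32-fold lower. The top 2% of genes by level had a median of -0.31 in this comparison. After quantile normalization the hypertrophy list median was -0.67, at percentile 0.08. Among 19 immediate early genes, 2 were lower and 0 higher (percentile 0.10), with Junb 4.08-fold and Atf3 3.39-fold lower. In the acute phase list, 5 of 41 genes were lower and 2 higher (percentile 0.34), with Cebpd 3.68-fold and Il6st at least 4.28-fold lower. Of 40 matrix genes, 10 were lower and 2 higher (percentile 1.34), including Timp3 (3.73-fold), an inhibitor of metalloproteinases bound to the matrix, Thbs4 (3.62-fold) and Tgfb2 (3.56-fold), a profibrotic growth factor. Hmox1 was 2.96-fold lower. Of 28 fatty acid oxidation genes, 2 were higher and 1 lower (percentile 99.15), with the hydratase Echs1 2.08-fold higher and Pdk4 2.78-fold lower. The 8 fibroblast markers had 0 genes past 2-fold (percentile 99.82), and Lum, a collagen-binding proteoglycan, was 1.84-fold higher.

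The cell cycle list had 2 of 19 genes higher and 1 lower (median -0.52, percentile 0.63), with Pcna 3.04-fold higher and Ccng1, a cyclin of the p53 response, 2.39-fold lower. Red cell and platelet markers had 2 of 6 lower and 0 higher (median -0.61, percentile 0.34), with Alas2, the heme synthesis enzyme of red cells, 2.39-fold lower. Smooth muscle markers had 2 of 5 lower (median -0.79, percentile 1.18), with Des, the intermediate filament desmin, 2.12-fold lower. Des also stands on the contraction list, so it is not specific to smooth muscle. Acta2, smooth muscle alpha-actin, had a log2 difference of 0.25 on the probe set used and of -0.67 and -1.72 on its other probe sets. Of 3 atrial markers, 1 was lower, Nppa (median -0.86, percentile 1.49). Contraction and calcium handling genes had 2 of 19 lower and 0 higher (median -0.44, percentile 0.21), with the calcium release channel Ryr2 2.12-fold lower. That median was 0.13 after quantile normalization and lay inside the random range, as it did after cyclic loess. The dTGR array differed from the losartan array in fluidics protocol and chip lot.

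Among 3644 genes, 215 were at least 2-fold higher after losartan and 346 lower, where probe set spread alone (SD 0.60) would give 154.1 and 155.0. Above the floor on both arrays were 147 higher and 187 lower genes, where the simulation gave 125.1 and 126.7, a smaller excess. Another probe set had the same sign in 72 of 93 called genes (77.4%). Quantile normalization gave 275 and 284, and scaling to the same median gave 340 higher and 219 lower. Further strongly lower genes were Cited2, Med25, Emp1, Akt2, Apbb1, Hbe2 and Gja4, a gap junction protein of endothelium, from 4.15-fold to 5.64-fold. The most strongly higher were Casz1, Lrba, Hs6st1, Gng10, Id2, Slc25a14, Myo5b, Hspa4, Dtd1 and Abcc6, from 3.25-fold to 5.61-fold. With the median of a gene's probe sets, the matrix, fatty acid oxidation, fibroblast, atrial and smooth muscle medians lay inside the random range. A floor at the 25th percentile put the acute phase, atrial and smooth muscle medians inside it, and a floor at the 60th percentile did so for the acute phase and smooth muscle lists.

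The genes that distinguished dTGR from SD control lay nearer to SD control after losartan. The 278 genes that were higher in dTGR had a median of 1.28 there and of 0.10 in losartan-treated dTGR, both against SD control, and 265 of them (95.3%) lay nearer to SD control than in dTGR. The 212 genes that were lower had medians of -1.23 and -0.36, and 191 (90.1%) lay nearer. Genes picked on the dTGR array move back toward the control by chance, and with simulated arrays that hold no effect the medians after treatment were 0.49 and -0.76 and the shares nearer to SD control 89.3% and 79.7%. For 84 of the 278 higher genes, SD control and losartan-treated dTGR both lay under the floor, so their difference was 0. The 127 higher genes above the floor on all 3 arrays had a median of 0.43 after losartan, and 122 (96.1%) lay nearer, where the simulation gave 0.56 and 88.2%. The 130 such lower genes had a median of -0.27, and 123 (94.6%) lay nearer, where the simulation gave -0.70 and 84.1%. The SD control and losartan arrays shared a fluidics protocol that the dTGR array did not, so an effect of protocol on the dTGR array would give the same return, and neither the simulation nor another probe set separates it from the treatment. Where 1 probe set picked the gene and another measured it, the medians were 0.34 in dTGR and 0.00 after losartan for 71 higher genes, and -0.16 and -0.03 for 69 lower genes. That check took probe sets above the floor on any array. The 0.00 can thus stand for values at the floor on both the SD control and losartan arrays, and not for a measured return.

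**Figure D2:**
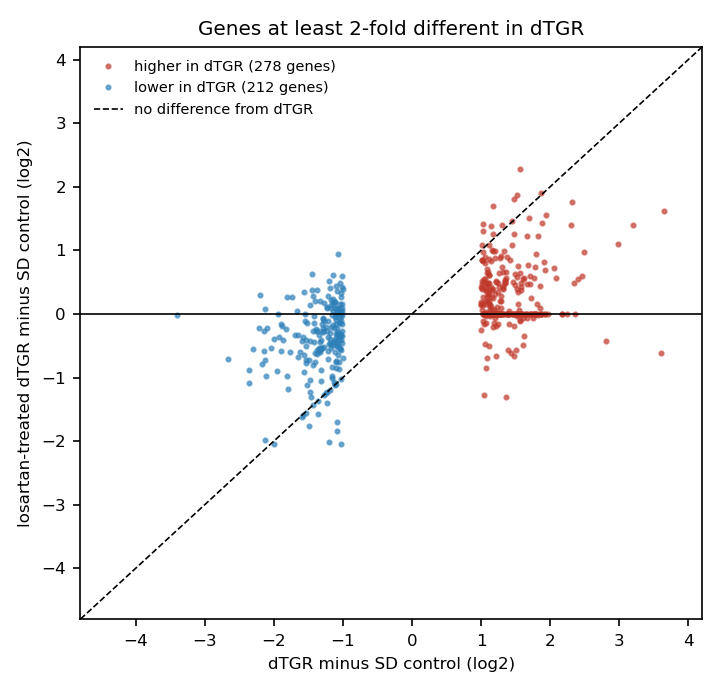
Log2 difference from SD control in dTGR (x axis) and in losartan-treated dTGR (y axis) for the 278 genes at least 2-fold higher (red) and the 212 at least 2-fold lower (blue) in dTGR, 1 point per gene and 1 array per group. The dashed line marks no difference between treated and untreated dTGR, and 265 of the higher and 191 of the lower genes lie nearer to 0 on the y axis than on the x axis.

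The fifth comparison set losartan-treated dTGR against SD control and asked what differed from the control under treatment. Some differences named below, such as that of Nppa, were present in untreated dTGR too, but others were not. Akt2 had a log2 difference of 0.31 from SD control in untreated dTGR and of -2.005 after losartan. The red cell and platelet list had medians of 0.25 and -0.53. It had the fewest genes past 2-fold of the 5 comparisons, with 76 higher and 165 lower among 3394, where probe set spread alone (SD 0.52) would give 86.5 and 86.6, so the number of higher genes did not exceed that of spread alone. Above the floor on both arrays were 47 higher and 117 lower genes, where the simulation gave 76.2 and 76.0. Nppa was still 3.07-fold higher than in SD control, at 5403 against 1759, while Nppb was 1.03-fold lower and Acta1 1.42-fold higher. Cebpb was 3.49-fold higher. Gja1, which encodes the main gap junction protein of the ventricle, was 5.92-fold lower, and Nr3c1, the glucocorticoid receptor, was 4.13-fold lower.

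Of 31 oxidative phosphorylation genes, 1 was higher and 0 lower (median 0.31, percentile 99.67), with Cox5a, a subunit of cytochrome c oxidase, 2.66-fold higher. Glycolysis genes had 3 of 21 lower and 0 higher (median -0.16, percentile 2.30), with Aldoa 2.74-fold and Hk1, a hexokinase, 2.32-fold lower. Red cell and platelet markers had 1 of 6 lower (median -0.53, percentile 0.28), with Alas2 2.08-fold lower. The abundant beta-globin genes of that list went the other way, with Hbb 1.24-fold and Hbb-b1 1.26-fold higher (both picked after their values were seen). The list of 18 cell cycle genes had 1 higher and 2 lower (median -0.33, percentile 0.98), with Cdc20 1.88-fold lower, and the 7 clock genes had 1 lower (median -0.58, percentile 2.27), with Dbp, an output factor of the clock, 3.27-fold lower. Genes of the insulin-like growth factor and growth hormone axis had 4 of 27 lower and 0 higher (median -0.25, percentile 2.46), with Akt2, a kinase of insulin signalling, 4.01-fold lower. The 6 smooth muscle markers had 0 genes past 2-fold (median -0.42, percentile 1.91), with Acta2, smooth muscle alpha-actin, 1.45-fold lower. The 7 cardiomyocyte markers had 0 genes past 2-fold (median 0.39, percentile 97.72), and lay inside the random range after quantile normalization (0.04) and cyclic loess (0.14). In this comparison the top 2% of genes by level had a median of 0.29.

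Another probe set had the same sign in 27 of 36 called genes (75.0%). Other strongly higher genes were Begain, Usp19, Cd1d1, Pitx3, Dnaaf9, Map3k9, Cct6a and Foxm1, from 2.69-fold to 4.88-fold, and the most strongly lower were Gstk1, Med25, Apbb1, Emp1, Timp3, Cited2, Hand2 and Pdk4, from 4.02-fold to 20.4-fold. Gstk1 had the upper value, with a log2 difference of -0.14 on another probe set. Begain, the gene with the largest higher value, went the other way on another probe set. Its log2 difference there was -1.025, a bound since the losartan value lay under the floor. The ratio of 3' to 5' signal of Gapdh was 2.17 on the losartan array and 1.34 on the SD control array, and those of actin were 2.26 and 1.46. Of the 8 lists outside the random range, the red cell list alone stayed outside it under all 9 alternative settings. Quantile normalization put the oxidative phosphorylation median inside it, cyclic loess the clock and cell cycle medians, a floor at the 60th percentile the smooth muscle median and the median of a gene's probe sets the cell cycle median. Both other floors and the median of a gene's probe sets did so for glycolysis, and scaling to the same median, a floor at the 60th percentile and the median of a gene's probe sets for the growth factor axis. Quantile normalization gave 97 higher and 138 lower.

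Across 3806 genes, the differences of dTGR and of terminal heart failure from SD control had a Pearson correlation of 0.38, those of dTGR and losartan-treated dTGR of 0.32, and those of terminal heart failure and losartan-treated dTGR of 0.34. These pairs share the SD control array, and simulated arrays with no effect gave 0.50 for each pair, so these correlations did not exceed that of a shared array. The covariance minus its simulated value was 0.05 for the first pair, -0.02 for the second and -0.01 for the third. Pairs that share no array gave a correlation of 0.14 for dTGR minus SD control with terminal minus losartan-treated, 0.11 for terminal minus SD control with dTGR minus losartan-treated, and 0.04 for losartan-treated minus SD control with terminal minus dTGR, against simulated values near 0. These 6 correlations are across genes, which are not independent replicates.

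On the dTGR and the terminal heart failure arrays, 20 genes were at least 2-fold above both the SD control and the losartan array, and 25 were below both, where a simulation with no effect gave 3.06. The other 2 ways to pair the arrays gave 23 genes (terminal with losartan, the chip lot pair) and 16 genes (terminal with SD control), so part of the excess over the simulation was not specific to this pair. The higher genes included Nppa, Reg3b, Penk, Atf3, Cebpd, Hmox1, Il6st, Spp1, Timp1, Thbs4 and Tpm2, and the lower genes included Col15a1, Eno3 and Bmyc.

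**Figure D3:**
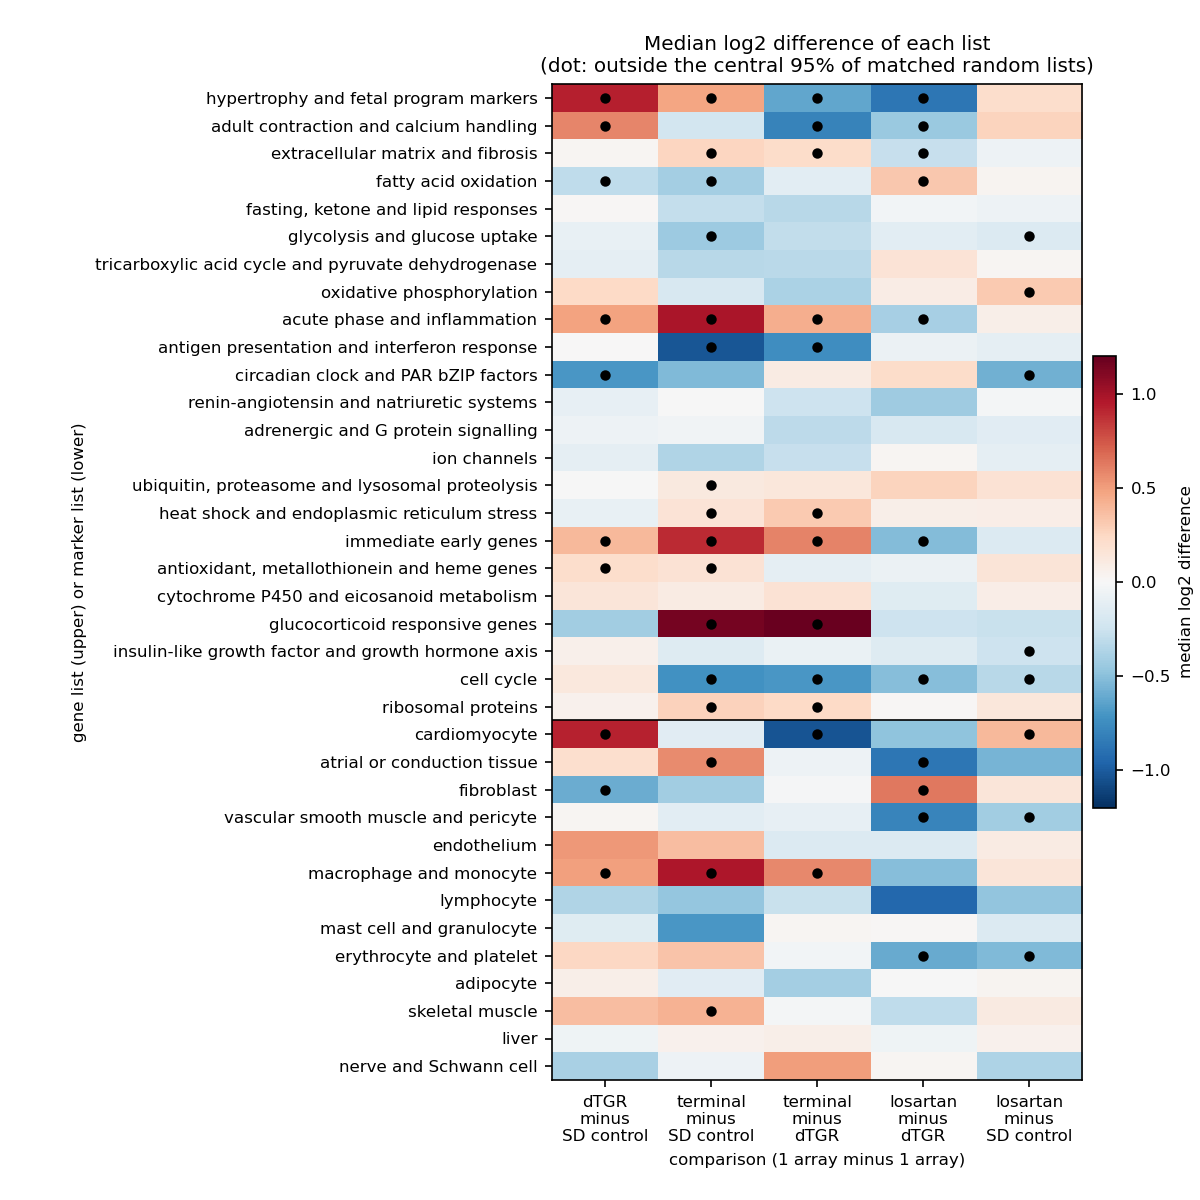
Median log2 difference (colour) of each of 23 gene lists and 13 cell type marker lists (y axis, line between both kinds) in the 5 comparisons (x axis), with a dot where the median lay outside the central 95% of 10000 random lists matched on size and level. Dots number 10, 16, 12, 11 and 8 from left to right, and the acute phase list was higher in both disease arrays (0.49 and 0.98 against SD control) and lower after losartan (-0.39 against dTGR).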

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

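Reading low values as 1 decimal was chosen after the data were seen, and the other settings before. The values as deposited, cyclic loess, quantile normalization, the median of a gene's probe sets and low values read as 1 decimal kept all 10 gene counts within 1.5 times the reported count, and the 9 settings applied to them left all 45 counts of lists outside the random range, 36 values on the return toward SD control and 54 correlations within their limits. Counts of other settings are given as higher and lower genes for dTGR against SD control, terminal heart failure against SD control, terminal heart failure against dTGR, losartan-treated against untreated dTGR and losartan-treated dTGR against SD control, in that order. With the floor at the 25th percentile they were 580 and 377, 350 and 455, 438 and 764, 418 and 651, and 224 and 308. With the floor at the 60th percentile they were 59 and 77, 142 and 141, 145 and 138, 90 and 94, and 27 and 61, since a lower floor lets more genes pass 2-fold and a higher floor fewer. Counting every probe set gave 533 and 376, 436 and 489, 516 and 737, 372 and 667, and 179 and 341, since more features than genes were counted. A 3-fold threshold gave 68 and 38, 82 and 72, 91 and 85, 37 and 94, and 17 and 37, as a stricter threshold must. Scaling to the same median gave 159 and 379 in the first, 442 and 226 in the third and 340 and 219 in the fourth. These comparisons hold the dTGR array, whose deposited median was 47.4 where the others had 38.7 to 40.2. That step thus lowered the whole dTGR array against the others. No floor with an offset gave 129 higher in the fifth, and the cause was not tested.

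Of 1616 list medians under alternatives, 1394 stayed within the spread of random lists, 216 moved further and 6 changed sign. After quantile normalization the contraction list was -0.072 in dTGR against SD control and 0.13 in losartan-treated against untreated dTGR, and the cardiomyocyte list was -0.10 in dTGR against SD control and 0.040 in terminal heart failure against dTGR. The hypertrophy list was 0.069 in terminal heart failure against dTGR after the same step. The cause of these changes after quantile normalization was not tested. In dTGR against SD control the antioxidant list was -0.034 after scaling to the same median, which lowers the whole dTGR array against SD control. Of 57 list medians outside the random range, 28 stayed outside it on the same side under every alternative run, 5 of 10, 11 of 16, 7 of 12, 4 of 11 and 1 of 8 in the 5 comparisons. Of 123 medians inside the range, 22 lay outside it under at least 1 alternative, 5 of them under 3 or more of 9: lymphocyte markers in losartan-treated dTGR against SD control (7) and in terminal heart failure against SD control (4), macrophage markers (5) and the renin-angiotensin list (3) in losartan-treated against untreated dTGR, and ion channels in losartan-treated dTGR against SD control (3). For the 203 reported differences of named genes of at least 2-fold, 1826 of 1827 values under alternatives had the same sign and 1764 were also at least 2-fold, the exception in sign being Actc1 in dTGR against SD control after quantile normalization (0.00). No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out of a group. Per array 58.4% to 63.7% of probe sets lay above the floor, and under it no difference was measured.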

Other observations

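Tests of the chip lot on the stress lists and of a lower share of cardiomyocytes were chosen after the result was seen, as were the pairings of arrays, the use of resampled ranges to judge the chip lot and the test of the losartan array against SD control. In terminal heart failure against SD control, genes of the renin-angiotensin, aldosterone, endothelin and natriuretic systems went both ways, with 4 of 25 higher and 4 lower (median -0.00, percentile 79.7). Adm, the vasodilator peptide adrenomedullin, was 4.49-fold higher, Ace, the enzyme that makes angiotensin II, 3.88-fold higher and Hsd11b1, which regenerates active glucocorticoid, 3.16-fold higher. After losartan against untreated dTGR, 0 of 27 of these genes were higher and 5 lower (median -0.42, percentile 3.53, but 2.35 after quantile normalization and 1.72 after cyclic loess, outside the random range). Adrenergic genes had 2 of 23 higher and 4 lower in terminal heart failure (median -0.04, percentile 76.4), with the receptor Adra1b 3.19-fold lower and the kinase Prkaca 3.73-fold lower. Among ion channel genes, 2 of 23 were higher and 4 lower (median -0.36, percentile 6.05), with Kcnj11, the pore of the ATP-sensitive potassium channel, 2.51-fold lower and the water channel Aqp1 2.33-fold higher. Eicosanoid and cytochrome P450 genes had 6 of 22 higher and 2 lower (median 0.10, percentile 94.9), with Pla2g4a 4.38-fold, Ptgds 4.25-fold and Alox15 2.81-fold higher. As reported, all of these medians lay inside the random range.

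Also against SD control, genes of fasting and ketone responses had 3 of 14 higher and 1 lower in terminal heart failure (median -0.28, percentile 25.7), with the lipid droplet protein Plin2 2.97-fold higher. The tricarboxylic acid cycle list had 0 of 17 genes past 2-fold (median -0.33, percentile 6.995), with the carrier Slc25a11 1.99-fold lower. Endothelial markers had 0 of 5 higher and 1 lower (median 0.37, percentile 94.0), lymphocyte markers 0 of 8 higher and 1 lower (median -0.46, percentile 6.13, but 2.04 after quantile normalization and 1.48 after cyclic loess, outside the random range), and mast cell and granulocyte markers 2 of 6 higher and 0 lower (median -0.70, percentile 3.91). S100a9, a calcium-binding protein of granulocytes, was 2.88-fold higher. Adipocyte markers had 1 of 6 higher and 0 lower (median -0.13, percentile 53.0), with Cfd, an adipocyte protease, 2.38-fold higher. Liver and nerve markers, of which 0 of 6 and 0 of 4 passed 2-fold, had medians of 0.05 and -0.06, and as reported all medians of this paragraph, too, lay inside the random range.

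Reg3b was 93.4-fold higher on the terminal array than in SD control. It is abundant in inflamed pancreas and in intestine, so RNA of either tissue in the sample could have brought it. Markers of pancreatic acinar cells had a median log2 difference of 0.0 over 15 genes and markers of intestinal epithelium a median of 0.0 over 13, with 0 genes of either list 2-fold higher and 4 and 5 above the floor on the terminal array. Their highest intensities on the terminal array were 62.1 (Sycn) and 76.2 (Slc5a1), against 3849 for Reg3b, which argues against either source. Expression of Reg3b in the ventricle itself stays open and was not tested, and the run day belonged to the terminal array alone.

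Contractile genes were higher on the dTGR array, but the 80 other genes of the top 2% by level had a median of 0.40 there, so other bright genes were higher too. Bright oxidative phosphorylation genes such as Cox6a2 (27691 in dTGR, log2 difference 1.07) were not left out of that comparison. More RNA of cardiomyocytes could raise such genes as well, so the 0.40 cannot tell a trend with level from it. The 11 contractile genes of that level had a median of 0.90, which is 0.50 more (0.16 to 0.71 when genes are resampled). Levels were not matched within the top 2%, so a steeper trend among the brightest genes could give this excess too. The test therefore cannot tell whether a part of it is specific to contractile genes. The median of the whole contraction list was -0.07 after quantile normalization, so the excess may also depend on the scaling. The other fluidics protocol belonged to this array alone and cannot be told apart from the dTGR group. More contractile transcript in hypertrophied muscle and an effect of that protocol on bright probe sets both stay open. The top 2% of genes by level also had a median of 0.29 on the losartan array against SD control, and these arrays had the same fluidics protocol.

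Stress genes were higher and antigen presentation genes lower on the terminal array, and over 59 members of the immediate early and acute phase lists the median against the losartan array of the same chip lot was 0.87, which argues against the lot for these genes. For the heat shock list the same median was 0.068 (-0.17 to 0.62 when genes are resampled), so for this list the lot cannot be told apart from the group, and for the antigen presentation list it was -0.72 (-1.16 to -0.18). Against SD control, the losartan array had medians of -0.058 for the immediate early and acute phase genes, 0.077 for the heat shock genes and -0.10 for the antigen presentation genes (-0.29 to 0.08), which argues against the lot for the median of the last list too, unless the treatment offset it. Single members can differ, since 3 of 19 antigen presentation genes were at least 2-fold lower there and 0 higher. A lower share of cardiomyocytes should raise the markers of other cell types alike, but their list medians ranged over 1.43, from -0.46 in lymphocytes to 0.97 in macrophages. The macrophage list shares Cd14 and Lgals3 with the acute phase list and Cd74 with the antigen presentation list. Lymphocyte markers such as Cd4 (40.1 on the terminal array) lay near the floor. Endothelial markers had a median of 0.37, but fibroblast and smooth muscle markers were not higher (-0.42 and -0.13). These medians argue against a lower share of cardiomyocytes as the whole explanation. Terminal disease, an acute stress before tissue collection and the separate run day stay open, and no test here separates them.

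On the arrays of the same chip lot, terminal and losartan, 6 genes were at least 2-fold above both others and 17 below both, where a simulation with no effect gave 2.98. Among the 17 were Dbp, Gstk1, Prkaca and, from the antigen presentation list, RT1-Ba (chosen after their values were seen). The remaining pairing, terminal with SD control, gave 11 and 5 genes (3.17 simulated).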
